A study of Rattus norvegicus with 21 samples.

How the data were processed

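The deposited processed files are 2 tables of 17085 gene symbols by 21 libraries. The first holds, per the labels, estimated counts from RSEM, which are whole numbers in the file, and the second the authors' length-scaled TPM, which sum to between 924400 and 972200 per library. The submitters' notes name STAR 2.7.3a for alignment, RSEM 1.3.1 for quantification and the rat genome rn7. Total RNA was isolated with RNeasy columns, libraries of mRNA were made with NEBNext Ultra and sequenced on an Illumina HiSeq. The gene annotation and the strandedness of the libraries were not given in the sources used here. Positions of genes were not used, since the gene table at hand belongs to another genome build. The labels do not say whether the 3 libraries of a group come from separate animals, and they were treated as such. The group field of the deposited labels shortens MI1h_R and MI6h_R, and the sample titles were followed.

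Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 7 groups, leaving 11742 genes, and scaled with TMM factors, which were 0.535 to 0.677 in Sham and 0.996 to 1.17 elsewhere. A quasi-likelihood model with 1 term per group was fitted to the 21 libraries together, and each of the 16 comparisons was a contrast of it. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called, by edgeR unless another tool is named, at an adjusted p under 0.05. Standard errors of log2 fold changes come from the coefficient and its F statistic. The smallest p of an exact permutation test of 3 libraries against 3 would be 0.1, so single values were not tested outside the models. CPM values use the TMM-scaled library sizes.

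The genes named were chosen by a rule set before the data were examined, as were the lists, the comparisons and all but 2 of the alternatives. It names Esrra, Esrrb, Esrrg, Ppara and Ppargc1a everywhere. In each comparison it adds up to 8 genes up and 8 down with the largest log2 fold change among called genes with a mean CPM of at least 10 and, for 2 groups, no overlap between them. For each list described it adds the members with the smallest p, or the members with the highest mean CPM where none was called. Where many genes were called a part of these is named, from the top of each order with some left out.

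The 51 lists held 796 symbols, of which 682 had a row under their symbol or 1 of 15 aliases and 652 were tested, and symbols without a row were not analysed here. Some genes sit on several lists, since Sdhb belongs to oxidative phosphorylation, the citric acid cycle and the reported ERR targets. The lists described in a comparison are a part of the 51, picked after their results were seen. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the lists. The tests of a list compare it with all other genes. With an estimated correlation only glycolysis and the hypoxia response kept their calls, in both late reperfusion comparisons against permanent ligation, and no list did in the other 14 comparisons.

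In 353 sets of symbols, 1131 in all and 492 of them tested, the counts were identical in every library, so such genes cannot be separated, and the repeated copies add 3.26% of all counts. Folds against a group with no count were bounded with a floor of 3 counts per library, and these bounds cover counting error only.

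Alternatives were DESeq2 1.42.0, limma-voom with quality weights, a limma trend on log2(TPM + 1), median-of-ratios factors, library size alone, no filter, no mitochondrial genes, only the groups compared, and each library left out in turn. Chosen after the data were seen were identical genes kept once and a smooth length trend removed from each library, with relative gene length taken from the ratio of counts to TPM. A term for equal replicate numbers was also tried. The numbers showed no pairing, with 1 of 12 libraries without F and 0 of 9 with F best correlated with the same number in another group. To test the procedure, all 21 libraries were simulated with 11742 genes from a shared mean profile. No other difference between groups was simulated, and all 21 were fitted together. Between MI1h_R and MI24h, 200 genes with a mean CPM of at least 10 were changed. edgeR found 123 of them with 2 false calls, limma-voom 123 with 3 and DESeq2 135 with 26. By size, edgeR found 2 of 50 genes changed 1.5-fold, 23 of 50 at 2-fold, 48 of 50 at 4-fold and 50 of 50 at 8-fold. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.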

Results

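The data were bulk RNA sequencing libraries of left ventricular infarct-zone tissue from Sprague Dawley rats, in 7 groups of 3. Sham hearts were the operated controls. In MI24h the left anterior descending coronary artery stayed ligated for 24 h. In MI1h_R the ligature was released after 1 h, followed by 23 h of reperfusion, and in MI6h_R after 6 h, followed by 18 h. The groups MI24h_F, MI1h_F and MI6h_F had the same 3 injuries with an added F. The design text mentions pretreatment with fenofibrate, an agonist of the fatty acid receptor PPARα, but the labels do not spell out F, and there is no Sham group with F. The series title concerns the estrogen-related receptors ERRβ and ERRγ, nuclear receptors that drive mitochondrial and contractile genes. Total counts per library ran from 12208041 to 18393795, and 11742 of 17085 gene symbols had enough counts to be tested. Transcripts of the mitochondrial genome took 36.3% ± 2.55 of the counts in Sham (SD, n = 3) and 16.2% ± 2.15 in MI24h (SD, n = 3). In the other 5 groups their mean share lay between 14.1% and 17.9%. The first principal component held 52.4% of the variance and put Sham apart from all injured groups.

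**Figure D1:**
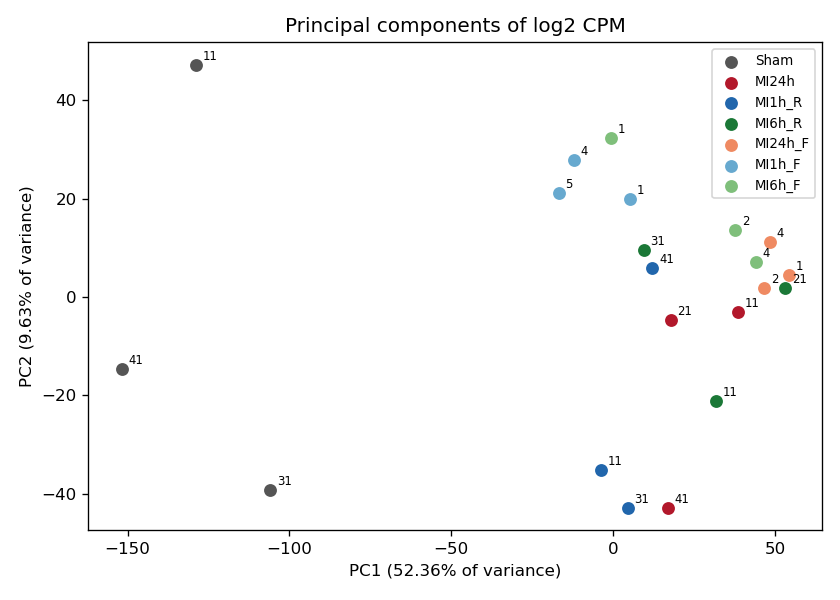
First and second principal components of log2 CPM (counts scaled to library size); each point is a library, labelled with its replicate number and coloured by group. The 3 Sham libraries lie between -152 and -106 on the first component, below the injured libraries.

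Permanent ligation was compared with Sham to ask what 24 h of infarction does to the transcriptome of the infarct zone. Genes of mitochondrial energy production fell throughout. In edgeR, Sdhb, a subunit of succinate dehydrogenase, had a log2 fold change of -2.53 ± 0.23 (SE, here and below), and Ndufs1 of complex I one of -3.16 ± 0.30. Fatty acid handling fell with them, with -2.85 ± 0.23 for the carnitine carrier Slc25a20, -3.07 ± 0.28 for the electron carrier enzyme Etfdh and -3.73 ± 0.39 for the β-oxidation enzyme Hadh. Among the regulators of these genes, Esrrg (ERRγ) fell by 2.20 ± 0.45 (edgeR adjusted p = 0.000462), the coactivator Ppargc1a (PGC-1α) by 3.53 ± 0.87 (adjusted p = 0.0022), Ppara by 2.67 ± 0.71 (adjusted p = 0.00411) and the muscle ERR partner Perm1 by 5.23. The fall in Esrrb (ERRβ), -1.33 ± 0.65, was not called (edgeR adjusted p = 0.0905), although it was called without Sham replicate 31. Without Sham replicate 11 Ppargc1a had -2.92 and Ppara -1.72, and on TPM both lost their calls. Esrra (ERRα) had -0.77 ± 0.16 (edgeR adjusted p = 0.000671), but this rested on the scaling, since it was -0.01 with library size alone and 0.26 on TPM.

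In the lists, all 32 nuclear genes of oxidative phosphorylation fell, 32 also when adjusted over the list alone (median log2 fold change -2.62, camera adjusted p = 1.29e-18). So did 21 of 21 citric acid cycle genes (21 adjusted over the list alone, median -2.44, camera adjusted p = 5.65e-14) and 21 of 22 reported ERR target genes (21 adjusted over the list alone, median -2.69, camera adjusted p = 1.95e-10). Of 22 fatty acid oxidation genes 21 fell and 1 rose (as adjusted over the list alone, median -3.06, camera adjusted p = 2.03e-11). Of 13 genes of the mitochondrial genome 12 fell (12 adjusted over the list alone, median -1.92, camera adjusted p = 1.14e-06). For these 5 lists camera gave an adjusted p = 0.244 with an estimated correlation. Of 28 PPARA target genes 22 fell and 3 rose, both also when adjusted over the list alone (median -2.69, camera adjusted p = 7.28e-07, and an adjusted p = 0.246 with an estimated correlation). Of 7 ERR receptors and coactivators 4 fell, 4 adjusted over the list alone (median -1.33, camera adjusted p = 0.0557).

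Cardiomyocyte transcripts fell as well, and transcripts of infiltrating leukocytes rose. The calcium-store protein gene Hrc fell by 4.17 ± 0.54 on the log2 scale, cardiac troponin I (Tnni3) by 3.54 ± 0.49, myoglobin (Mb) by 3.19 ± 0.45 and the fatty acid binding protein gene Fabp3 by 5.35 ± 0.78. The decoy interleukin-1 receptor Il1r2, carried by neutrophils, rose by 7.19 ± 0.80, the chemokine receptor Cxcr2 by 5.74 ± 0.67 and the gelatinase Mmp9 by 6.06 ± 0.72. Arg1 and Vcan, expressed by recruited macrophages, rose by 6.35 ± 0.62 and 4.24 ± 0.53. The cytokine gene Il6 rose by 7.53 ± 1.07, the neutrophil attractant Cxcl2 by 7.26 ± 1.03 and the growth factor Csf1 by 2.59 ± 0.18. Its relative Cxcl3 had no count in any Sham library and was at least 74.9-fold higher in MI24h, against a floor of 3 counts per library, or 44.2-fold without MI24h replicate 11. Stress genes rose as well, among them Asns of amino acid shortage (3.13 ± 0.30), the endoplasmic reticulum chaperones Pdia4 (2.30 ± 0.26) and Hspa5 (2.14 ± 0.28) and the AP-1 gene Fosl1 (5.68 ± 0.39). Glucose uptake and lactate export genes rose too, with 3.86 ± 0.37 for Slc2a1, 6.13 ± 0.70 for Slc16a3 and 2.34 ± 0.21 for the phosphofructokinase gene Pfkl. The collagen cross-linker Lox, induced by hypoxia, rose by 3.29 ± 0.39. Resting fibroblast genes fell, with -2.81 ± 0.25 for Gsn, -2.63 ± 0.35 for Dpt, -2.59 ± 0.39 for Col3a1 and -2.44 ± 0.41 for Lum. Among called genes with a mean CPM of at least 10 and no overlap between the groups, the muscle genes Asb10, a ubiquitin ligase part, and Ky, a sarcomere maintenance gene, had the largest falls, by 8.41 ± 1.32 and 7.40 ± 0.93. Without Sham replicate 31 the rises were 8.57 for Il1r2, 8.77 for Il6, 8.15 for Cxcl2, 6.87 for Mmp9, 4.89 for Vcan, 6.52 for Fosl1 and 7.56 for Slc16a3, and without MI24h replicate 11 they were 6.51 for Il1r2, 6.60 for Il6, 4.99 for Mmp9 and 4.55 for Cxcr2. Cxcl2 had 6.66 without Sham replicate 11 and Asb10 -9.24 without MI24h replicate 21.

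Of 14 cardiomyocyte markers 14 fell (14 adjusted over the list alone, median -3.18, camera adjusted p = 4.39e-07, and an adjusted p = 0.257 with an estimated correlation). Of 14 neutrophil markers 13 rose (13 adjusted over the list alone, median 4.94, camera adjusted p = 1.03e-06) and of 17 genes of the unfolded protein response 14 rose (14 adjusted over the list alone, median 1.63, camera adjusted p = 1.65e-05). Both had an adjusted p = 0.246 with an estimated correlation. Of 14 inflammatory cytokines 12 rose (12 adjusted over the list alone, camera adjusted p = 1.93e-05). Their median was 3.83, or 3.57 with Csf3, which had no count in Sham, at its bound. Of 18 immediate early genes 14 rose and 1 fell, as when adjusted over the list alone (median 1.53, camera adjusted p = 5.46e-05). For cytokines and immediate early genes camera gave an adjusted p = 0.244 with an estimated correlation. Of 20 monocyte and macrophage markers 12 rose and 3 fell, the same counts when adjusted over the list alone (median 2.00, camera adjusted p = 0.0078, and an adjusted p = 0.413 with an estimated correlation). Of 12 glycolysis genes 8 rose and 1 fell, as adjusted over the list alone (median 1.34, camera adjusted p = 0.00322, and an adjusted p = 0.274 with an estimated correlation). Of 19 hypoxia genes 11 rose and 1 fell, as adjusted over the list alone (median 1.57, camera adjusted p = 0.00958, and an adjusted p = 0.391 with an estimated correlation). Of 16 fibroblast markers 10 fell and 1 rose, as adjusted over the list alone (median -1.28, camera adjusted p = 0.00496, and an adjusted p = 0.366 with an estimated correlation). Of 11 endothelial markers 5 fell, 5 adjusted over the list alone (median -0.32, camera adjusted p = 0.0485, and an adjusted p = 0.402 with an estimated correlation), but their median was 0.39 with library size alone.

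In total 6371 genes were called between MI24h and Sham, 3293 up and 3078 down, and 4202 of them changed by at least 1 on the log2 scale. The split between directions rested on the scaling, where Sham has the largest mitochondrial share. With library size alone the median of all genes moved from 0.07 to 0.80 and 6484 genes were called up against 1504 down, and on TPM 7375 up against 1208 down (median 0.83).

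Early reperfusion was compared with Sham to ask what remains of the injury when the artery reopens after 1 h. Energy genes and cardiomyocyte genes were again lower, while inflammatory genes and genes of dividing cells were higher. Sdhb fell by 2.07 ± 0.23 on the log2 scale and Ndufs1 by 2.63 ± 0.29, and the complex III genes Cyc1 and Uqcrc1 by 2.27 ± 0.23 and 2.30 ± 0.24. The fatty acid transporter Slc27a1 fell by 1.81 ± 0.16, Slc25a20 by 2.52 ± 0.23 and Etfdh by 2.82 ± 0.27. Hrc, Mb and Tnni3 fell by 3.97 ± 0.53, 3.19 ± 0.45 and 3.32 ± 0.48, and Asb10 and the muscle ubiquitin ligase Trim50 by 6.33 each. Esrrb fell by 2.12 ± 0.67 (edgeR adjusted p = 0.0142), Esrrg by 2.15 ± 0.45, Ppara by 2.32 ± 0.70 (edgeR adjusted p = 0.0105), Ppargc1a by 2.51 ± 0.82 (edgeR adjusted p = 0.0164) and Perm1 by 4.69 ± 0.81. Esrra had -1.07 ± 0.16 (edgeR adjusted p = 4.35e-05). Library size alone took the call from Esrra (-0.27), Esrrb (-1.33), Ppargc1a (-1.73) and Ppara (-1.57), and so did TPM. Without Sham replicate 11 Esrrb, Ppargc1a and Ppara had -1.44, -1.89 and -1.37, and without MI1h_R replicate 41 Esrrb had -2.79. The monocyte attractants Ccl12 and Ccl2 rose by 6.42 ± 0.74 and 4.53 ± 0.72, the neutrophil alarmins S100a8 and S100a9 by 4.60 ± 0.71 and 3.93 ± 0.57, and Arg1 and the macrophage elastase Mmp12 by 4.81 ± 0.58 and 5.01 ± 0.93. The DNA replication helicase genes Mcm6, Mcm5 and Mcm2 rose by 2.62 ± 0.29, 2.45 ± 0.32 and 1.78 ± 0.24. Without Sham replicate 31 the Mmp12 fold (10.36) rested on 1 count in each other Sham library, and Ccl12 had 7.19, Ccl2 6.96, S100a8 5.26 and Mcm6 and Mcm5 3.27 each, and without Sham replicate 11 Mmp12 had 4.41.

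Of the lists, oxidative phosphorylation fell in 32 of 32 genes (32 adjusted over the list alone, median -2.27, camera adjusted p = 7.57e-18), the citric acid cycle in 21 of 21 (21 adjusted over the list alone, median -2.07, camera adjusted p = 1.3e-13) and reported ERR targets in 22 of 22 (22 adjusted over the list alone, median -2.55, camera adjusted p = 1.75e-11). Fatty acid oxidation had 21 down and 1 up of 22, as adjusted over the list alone (median -2.89, camera adjusted p = 1.75e-11). PPARA targets had 23 down and 3 up of 28, as adjusted over the list alone (camera adjusted p = 4.12e-08). Their median was -2.55, or -2.54 with Acaa1a, which had no count in MI1h_R, at its bound. These 5 lists had an adjusted p = 0.312 with an estimated correlation. ERR receptors and coactivators fell in 5 of 7, 6 adjusted over the list alone (median -2.12, camera adjusted p = 0.0214, and an adjusted p = 0.373 with an estimated correlation). Chemokines rose in 12 of 23 and fell in 3, with 12 and 5 adjusted over the list alone (camera adjusted p = 0.0311, and an adjusted p = 0.373 with an estimated correlation). Their median was 1.37, or 1.297 with Ccl17 and Cxcl3 at their bounds. Cardiomyocyte markers fell in 14 of 14 (14 adjusted over the list alone, median -3.02, camera adjusted p = 4.88e-07), neutrophil markers rose in 11 of 14 (12 adjusted over the list alone, median 3.69, camera adjusted p = 1.16e-05) and cell cycle genes in 17 of 19 (18 adjusted over the list alone, median 1.54, camera adjusted p = 1.87e-06). Monocyte and macrophage markers had 15 up and 2 down of 20, with 15 and 3 adjusted over the list alone (median 2.19, camera adjusted p = 0.00016). These 4 lists had an adjusted p = 0.331 with an estimated correlation. Glycolysis went both ways, with 4 up and 3 down of 12, as adjusted over the list alone (median 0.10, camera adjusted p = 0.923). Hypoxia genes did too, with 6 up and 8 down of 19, as adjusted over the list alone (camera adjusted p = 0.654). Their median was -0.30 and their mean 0.01, and the median was 0.47 with library size alone. In all, 5809 genes were called, 2980 up and 2829 down, 3715 of them by at least 1 on the log2 scale. Calls for Esrrb and Ppargc1a were lost without Sham replicate 11 or MI1h_R replicate 11 or 31, and that for Ppara without Sham replicate 11. With library size alone 6597 genes were up and 1273 down (median 0.82), and on TPM 6741 up and 1148 down (median 0.72).

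Late reperfusion was compared with Sham to ask the same after 6 h of ischemia. Energy and muscle genes were lower here as well, and genes of the interferon response were below their Sham level. Sdhb, the complex III gene Uqcrfs1 and the complex I gene Ndufs8 fell by 2.66 ± 0.23, 3.01 ± 0.28 and 2.89 ± 0.25 on the log2 scale. Mb and cardiac actin (Actc1) fell by 3.64 ± 0.46 and 3.72 ± 0.46, the insulin-dependent glucose transporter Slc2a4 by 6.45 ± 0.80, Asb10 by 6.95 ± 1.16 and Trim50 by 6.52 ± 0.99. Esrrg fell by 2.79 ± 0.46 (edgeR adjusted p = 5.55e-05), Ppargc1a by 3.10 ± 0.84 (edgeR adjusted p = 0.0042), Esrrb by 1.69 ± 0.65 (edgeR adjusted p = 0.0341), Ppara by 2.13 ± 0.69 (edgeR adjusted p = 0.0134) and Perm1 by 5.46 ± 0.84. Esrra had -0.89 ± 0.16 (edgeR adjusted p = 0.000166), which became -0.01 with library size alone and 0.33 on TPM, and library size alone also took the calls from Esrrb (-0.86) and Ppara (-1.33). The neutrophil genes Il1r2 and Cxcr2 rose by 6.95 ± 0.80 and 5.52 ± 0.66, the leukotriene receptor Ltb4r by 6.14 ± 0.48 and Ccl12 by 6.07 ± 0.73. Arg1 and the macrophage mannose receptor Mrc1 rose by 6.16 ± 0.61 and 2.41 ± 0.33, and Fosl1 by 5.65 ± 0.39. The interferon-induced genes Usp18, Gbp4 and Ifi27 fell by 3.32 ± 0.85, 3.62 ± 0.93 and 2.26 ± 0.59, calls that TPM took, along with those of Esrrb and Ppara. Without MI6h_R replicate 31 Asb10 had no count in MI6h_R, and Trim50 had -8.43, Slc2a4 -7.63, Perm1 -6.35, Ppargc1a -5.21 and Ppara -3.12. Without Sham replicate 31 Il1r2 had 8.35, Ccl12 6.86 and Fosl1 6.52, and without Sham replicate 11 Usp18 had -2.56, Gbp4 -1.84, Ppargc1a -2.47, Ppara -1.17 and Esrrb -0.99. Asb10 had -6.32 without MI6h_R replicate 11.

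Oxidative phosphorylation fell in 32 of 32 genes (32 adjusted over the list alone, median -2.81, camera adjusted p = 5.06e-19), the citric acid cycle in 21 of 21 (21 adjusted over the list alone, median -2.50, camera adjusted p = 2.57e-13) and fatty acid oxidation in 21 of 22 with 1 up, as adjusted over the list alone (median -3.12, camera adjusted p = 2.91e-11). These 3 lists had an adjusted p = 0.3 with an estimated correlation. Reported ERR targets fell in 22 of 22 (22 adjusted over the list alone, median -3.07, camera adjusted p = 2.91e-11, and an adjusted p = 0.304 with an estimated correlation). Cardiomyocyte markers fell in 14 of 14 (14 adjusted over the list alone, median -3.85, camera adjusted p = 6.51e-08), neutrophil markers rose in 12 of 14 (12 adjusted over the list alone, median 4.67, camera adjusted p = 3.96e-06) and PPARA targets had 22 down and 3 up of 28, as adjusted over the list alone (median -2.81, camera adjusted p = 4.61e-06). These 3 had an adjusted p = 0.357 with an estimated correlation. Monocyte and macrophage markers had 14 up and 3 down of 20, with 15 and 3 adjusted over the list alone (median 1.94, camera adjusted p = 0.0013, and an adjusted p = 0.422 with an estimated correlation). Interferon response genes fell in 15 of 21 (16 adjusted over the list alone, median -2.59, camera adjusted p = 0.00942, and an adjusted p = 0.664 with an estimated correlation). ERR receptors and coactivators fell in 5 of 7, 5 adjusted over the list alone (median -1.69, camera adjusted p = 0.0555). Glycolysis had 6 up and 4 down of 12, as adjusted over the list alone (median 0.37, camera adjusted p = 0.596). Hypoxia genes had 7 up and 7 down of 19, as adjusted over the list alone (camera adjusted p = 0.912), with a median of -0.06 and a mean of 0.14, and a median of 0.80 with library size alone. In all, 6721 genes were called, 3438 up and 3283 down, 4497 of them by at least 1 on the log2 scale. The call for Esrrb was lost without Sham replicate 11 or 41 or MI6h_R replicate 11 or 21. That for Ppara was lost without Sham replicate 11 or MI6h_R replicate 11 or 21, and that for Gbp4 without Sham replicate 11. With library size alone 6878 genes were up and 1510 down (median 0.91), and on TPM 7946 up and 1172 down (median 0.99).

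**Figure D2:**
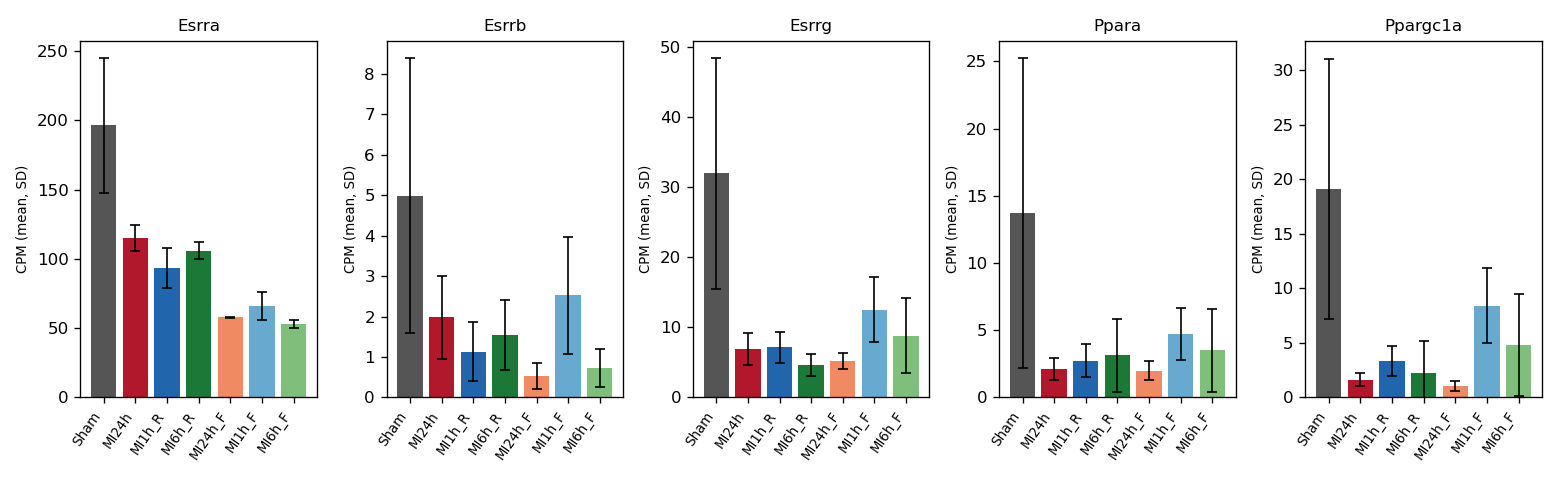
CPM of Esrra, Esrrb, Esrrg, Ppara and Ppargc1a in each group; bars are means and error bars the SD over 3 libraries. Esrra falls from 196 in Sham to 115 in MI24h and 57.8 in MI24h_F, and Ppargc1a from 19.2 in Sham to 1.65 in MI24h, although the Esrra step from Sham vanishes with library size scaling.

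Early reperfusion was compared with permanent ligation to ask what reopening the artery after 1 h spares. Genes of glycolysis, oxygen shortage and acute inflammation were lower, and genes of dividing cells were higher. The glucose transporter Slc2a1 fell by 2.47 ± 0.35 on the log2 scale, Pfkl by 1.98 ± 0.21, the glycolytic enzymes Tpi1 and Gpi by 1.14 ± 0.20 and 1.07 ± 0.19, and Slc16a3 by 2.82 ± 0.58. The oxygen-sensing hydroxylases Egln1 and Egln3 fell by 1.33 ± 0.19 and 2.75 ± 0.47, the vasodilator gene Adm by 2.65 ± 0.38 and the vessel growth genes Vegfa and Angpt2 by 1.93 ± 0.34 and 2.24 ± 0.30. The cytokine genes Il6 and Lif fell by 4.40 ± 0.79 and 4.21 ± 0.82, the attractants Cxcl3 and Cxcl2 by 3.96 ± 0.76 and 3.27 ± 0.72, and the stress kinase-like Trib3 and the chaperone Hspa5 by 2.80 ± 0.50 and 1.05 ± 0.28. The mitosis genes Bub1, Nusap1 and Mki67 rose by 1.23 ± 0.24, 1.85 ± 0.42 and 1.52 ± 0.36. The macrophage genes Igf1 and Mrc1 rose by 1.52 ± 0.24 and 1.49 ± 0.32 while the clotting factor gene F13a1 fell by 2.18 ± 0.35. The smooth muscle genes Tagln and Actg2 rose by 2.20 ± 0.34 and 3.29 ± 0.56, and Cd8a by 2.32 ± 0.61. The very short transcripts Rpl41, ATP8 and Rps28 rose by 3.89 ± 0.62, 3.32 ± 0.66 and 2.56 ± 0.61. Without MI1h_R replicate 41 these 3 had 2.45, 1.79 and 1.72, and Lif -4.82. Without MI24h replicate 11 Il6 had -3.46, Cxcl3 -3.20 and Lif -3.15, without MI1h_R replicate 31 Il6 -5.05 and Cxcl3 -4.80, and without MI24h replicate 21 Cd8a 3.28. None of the receptor genes was called by edgeR, with -0.30 ± 0.16 for Esrra, -0.79 ± 0.67 for Esrrb, 0.06 ± 0.44 for Esrrg, 0.35 ± 0.71 for Ppara and 1.02 ± 0.84 for Ppargc1a.

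Glycolysis fell in 9 of 12 genes (12 adjusted over the list alone, median -1.11, camera adjusted p = 8.74e-13) and the hypoxia response in 13 of 19 (15 adjusted over the list alone, median -1.28, camera adjusted p = 7.73e-14), both with an adjusted p = 0.0714 with an estimated correlation. Cell cycle genes rose in 5 of 19 (14 adjusted over the list alone, median 1.08, camera adjusted p = 4.39e-10, and an adjusted p = 0.312 with an estimated correlation). The unfolded protein response fell in 5 of 17 (8 adjusted over the list alone, median -0.81, camera adjusted p = 1.86e-05, and an adjusted p = 0.402 with an estimated correlation). Inflammatory cytokines fell in 3 of 14, with 7 down and 1 up adjusted over the list alone (median -1.03, camera adjusted p = 0.00101, and an adjusted p = 0.367 with an estimated correlation). Resident macrophage markers had 3 up and 1 down of 10, as adjusted over the list alone (median 0.59, camera adjusted p = 0.00621), and angiogenesis genes 5 down of 18, with 7 down and 1 up adjusted over the list alone (median -0.54, camera adjusted p = 0.00395), both with an adjusted p = 0.188 with an estimated correlation. No gene of oxidative phosphorylation was called by edgeR, of 32 tested and 0 adjusted over the list alone (median 0.34, camera adjusted p = 0.000144, and an adjusted p = 0.89 with an estimated correlation), and its most abundant member Atp5f1b, the ATP synthase β subunit gene, had 0.17 ± 0.27. In all 507 genes were called, 177 up and 330 down, 313 of them by at least 1 on the log2 scale, and on TPM 122 up and 400 down. The count was 68 without MI24h replicate 11, and 185, 103 and 943 without MI1h_R replicates 11, 31 and 41. Of the 28 named genes that were called, 16 kept their call whichever library was left out, among them Il6, Slc2a1, Pfkl, Vegfa, Igf1 and Rpl41. All 28 calls were lost when edgeR was fitted to only the groups compared, which called 0 genes, while DESeq2 on all groups called 1047 and limma-voom 1509. Leaving out MI24h replicate 11 ended 12 calls, including Cxcl2, Cxcl3, Lif, Slc16a3, Bub1, Nusap1, Mki67, Mrc1, ATP8 and Rps28. MI1h_R replicates 31 and 11 ended 8 and 6. MI24h replicate 41 ended 3, MI1h_R replicate 41 and MI1h_F replicate 4 ended 2 each, and MI24h replicate 21, MI6h_R replicate 11 and MI24h_F replicate 2 ended 1 each.

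The same comparison in the groups with F asked whether early reperfusion acts alike there. Cardiomyocyte and oxidative genes were higher after early reperfusion in these groups, and inflammatory and hypoxia genes were lower. Actc1 rose by 2.11 ± 0.43 on the log2 scale, the small muscle protein gene Smpx by 1.78 ± 0.36, Tnni3 by 2.06 ± 0.46, Fabp3 by 3.11 ± 0.70, Slc2a4 by 3.57 ± 0.74 and phospholamban (Pln) by 3.25 ± 0.96. The respiratory genes Ndufa8 and Cox5b rose by 1.37 ± 0.23 and 1.35 ± 0.27, and the fatty acid oxidation genes Cpt1b and Etfb by 2.64 ± 0.57 and 1.49 ± 0.32. Among the regulators Ppargc1a rose by 2.97 ± 0.88 (edgeR adjusted p = 0.0295), Esrrb by 2.24 ± 0.72 (edgeR adjusted p = 0.0421) and Perm1 by 2.88 ± 0.78 (edgeR adjusted p = 0.02), while Esrrg had 1.25 ± 0.44 (edgeR adjusted p = 0.0635), Ppara 1.23 ± 0.71 and Esrra 0.19 ± 0.16. Slc2a1 fell by 2.74 ± 0.35, the oxygen-sensing factor Hif1a by 1.66 ± 0.28 and Vegfa by 1.78 ± 0.34. Il6 and Cxcl2 fell by 5.96 ± 0.88 and 4.22 ± 0.76, the neutrophil genes Camp and Il1r2 by 2.84 ± 0.46 and 3.60 ± 0.64, Arg1 by 3.81 ± 0.53 and the interferon gene Ifit3 by 3.87 ± 0.88. In all 1832 genes were called, 1041 up and 791 down, with 1041 changed by at least 1 on the log2 scale, and on TPM 1280 up and 566 down. The count was 644 and 788 without MI1h_F replicates 4 and 5, and 681, 907 and 1116 without MI24h_F replicates 1, 2 and 4. Each of these 5 omissions ended the calls of Pln, Ppargc1a, Esrrb and Perm1, while Esrrg gained a call without Sham replicate 11, MI1h_F replicate 1 or MI6h_F replicate 1, and with DESeq2 or limma-voom. Cxcl2 and Il1r2 had -5.20 and -4.27 without MI1h_F replicate 5, Ifit3 -3.06 without MI24h_F replicate 1 and Esrrb 2.88 without MI24h_F replicate 2.

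Cardiomyocyte markers rose in 14 of 14 (14 adjusted over the list alone, median 2.07, camera adjusted p = 4.46e-09), oxidative phosphorylation in 25 of 32 (29 adjusted over the list alone, median 0.98, camera adjusted p = 5.17e-13), the citric acid cycle in 15 of 21 (18 adjusted over the list alone, median 0.80, camera adjusted p = 8.23e-09) and fatty acid oxidation in 14 of 22 (17 adjusted over the list alone, median 1.18, camera adjusted p = 1.21e-07). Neutrophil markers fell in 9 of 14 (11 adjusted over the list alone, median -2.03, camera adjusted p = 1.83e-07). These 5 lists had an adjusted p = 0.284 with an estimated correlation. Reported ERR targets had 16 up and 1 down of 22, with 18 and 1 adjusted over the list alone (median 1.21, camera adjusted p = 1.98e-07, and an adjusted p = 0.303 with an estimated correlation). ERR receptors and coactivators rose in 3 of 7, 4 adjusted over the list alone (median 1.25, camera adjusted p = 0.0234, and an adjusted p = 0.322 with an estimated correlation). Glycolysis fell in 9 of 12 (10 adjusted over the list alone, median -1.03, camera adjusted p = 1.2e-07), the hypoxia response in 12 of 19 (16 adjusted over the list alone, median -1.20, camera adjusted p = 2.62e-10) and inflammatory cytokines in 8 of 14 (11 adjusted over the list alone, median -1.78, camera adjusted p = 3.01e-07), each with an adjusted p = 0.181 with an estimated correlation. Interferon response genes fell in 3 of 21 (8 adjusted over the list alone, median -1.96, camera adjusted p = 0.000587, and an adjusted p = 0.468 with an estimated correlation), and their mean log2 CPM spread from 4.07 to 7.24 in MI24h_F, around the 4.20 to 4.48 of MI1h_F.

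The comparisons with and without F share no library. Of the 507 genes called for early reperfusion without F, 453 had the same sign with F, and 65 were called up and 188 down in both, against 15.7 and 22.2 by chance. Across all 11742 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.451. Of the 6371 genes called between MI24h and Sham, 80.7% moved towards their Sham level in MI1h_F against MI24h_F, with a median ratio of -0.305 to the injury change, and 1474 of these moves were called against 24 in the other direction. In MI6h_F against MI24h_F the share was 74.4% with a median ratio of -0.135, and 63% without MI6h_F replicate 1. Both shares start from the low MI24h_F level.

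**Figure D3:**
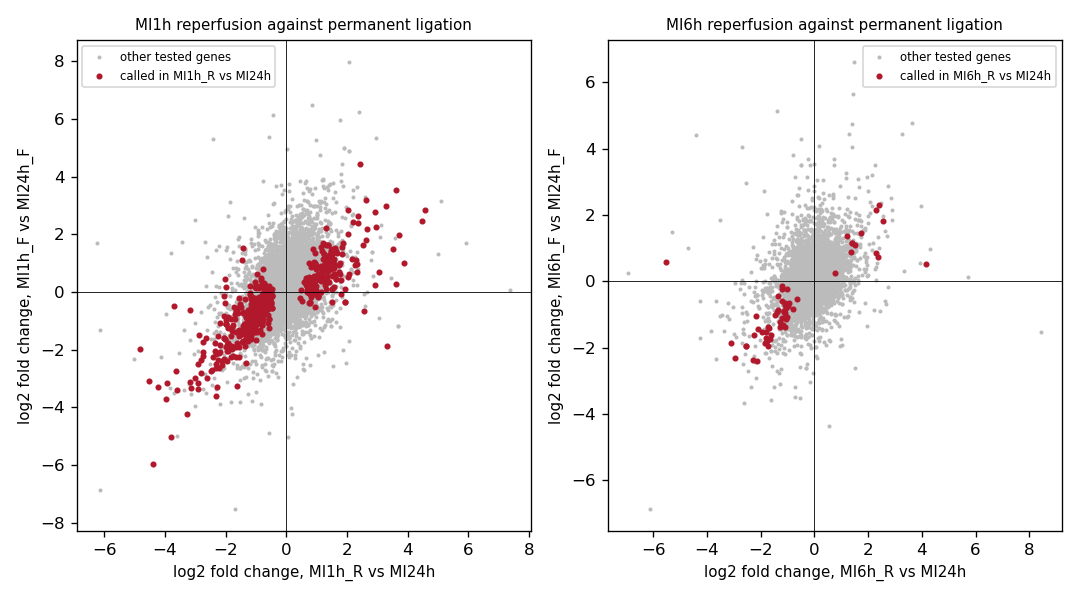
Log2 fold changes of reperfusion against permanent ligation, without F on the horizontal and with F on the vertical axis; each point is a tested gene and red points were called without F. The left panel shows early and the right panel late reperfusion, and most red points, 453 of 507 and 58 of 59, keep their sign.

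Late reperfusion was compared with permanent ligation to ask what opening the artery after 6 h changes. Hypoxia and glycolysis genes were lower. The scavenger receptor Cd163 rose by 4.16 ± 0.61 on the log2 scale, Mrc1 by 2.57 ± 0.33, the macrophage lectin Clec10a by 2.36 ± 0.33 and Igf1 by 1.39 ± 0.24, while F13a1 fell by 2.14 ± 0.35. Egln3 and Egln1 fell by 3.12 ± 0.48 and 1.07 ± 0.19, Tpi1 and the phosphofructokinase Pfkp by 1.29 ± 0.20 and 1.03 ± 0.17, Slc2a1 by 1.77 ± 0.34 and Vegfa by 1.79 ± 0.33. The hypoxia-induced cell death gene Bnip3 fell by 1.80 ± 0.36, the oxidase Ero1a by 1.85 ± 0.38, the chemokine receptor Cxcr4 by 1.93 ± 0.24 and the T cell attractant Cxcl9 by 2.16 ± 0.44. No interferon gene was called by edgeR, with -1.51 ± 0.58 for Ifi27 (adjusted p = 0.397) and -3.27 ± 1.01 for the master regulator Irf7 (adjusted p = 0.214). Neither were the receptor genes, with -0.12 ± 0.16 for Esrra, -0.36 ± 0.65 for Esrrb, -0.58 ± 0.44 for Esrrg, 0.54 ± 0.70 for Ppara and 0.43 ± 0.84 for Ppargc1a. Glycolysis fell in 5 of 12 (11 adjusted over the list alone, median -1.02, camera adjusted p = 8.21e-19) and the hypoxia response in 8 of 19 (14 adjusted over the list alone, median -1.21, camera adjusted p = 2.38e-20), and both calls held, with an adjusted p = 0.016 with an estimated correlation. Resident macrophage markers had 3 up and 1 down of 10, as adjusted over the list alone (median 0.17, camera adjusted p = 0.00471, and an adjusted p = 0.282 with an estimated correlation). DESeq2 called Irf7 and Hspa5. With 0 of 21 members called by edgeR, the interferon response had 19 down adjusted over the list alone (median -2.66, camera adjusted p = 6.23e-16, and an adjusted p = 0.465 with an estimated correlation). The unfolded protein response, with 0 of 17 called by edgeR and Hspa5 at -1.08 ± 0.28, had 10 down adjusted over the list alone (median -0.77, camera adjusted p = 7.32e-10, and an adjusted p = 0.306 with an estimated correlation). Oxidative phosphorylation had 0 of 32 called and 0 adjusted over the list alone, with Atp5f1b at -0.32 ± 0.27 (median -0.27, camera adjusted p = 3e-04, and an adjusted p = 0.839 with an estimated correlation).

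In all 59 genes were called between MI6h_R and MI24h, 13 up and 46 down, 54 of them by at least 1 on the log2 scale. On TPM 22 were up and 25 down, where the median of all genes was 0.16. The count was 14, 110 and 33 without MI24h replicates 11, 21 and 41, and 17 and 21 without MI6h_R replicates 21 and 31. Cd163, Mrc1, Clec10a, Egln3, Tpi1 and Cxcr4 kept their calls whichever library was left out. A fit of only the groups compared lost 11 of the 15 named calls, Egln3 and Tpi1 included. The other 9 named calls were lost without MI6h_R replicate 21, 7 without MI24h replicate 11, where Ero1a had -1.19, 6 without MI6h_R replicate 31 and 3 without MI24h replicate 41 or MI6h_R replicate 11. In the groups with F, late reperfusion lowered the same kind of genes, with -1.80 ± 0.34 for Slc2a1, -1.31 ± 0.21 for Pfkl, -1.21 ± 0.20 for Tpi1, -1.74 ± 0.28 for the enolase Eno2, -1.72 ± 0.33 for Vegfa and -1.87 ± 0.38 for Ero1a. F13a1 and the transcription repressor Prdm1 fell by 2.41 ± 0.35 and 1.95 ± 0.27. Mrc1 and Igf1 rose by 1.81 ± 0.32 and 1.15 ± 0.24, Tagln by 2.18 ± 0.35, the artery connexin Gja5 by 1.89 ± 0.37 and the transporter-like Slc26a10 by 3.14 ± 0.61. None of the receptor genes was called by edgeR, with -0.12 ± 0.16 for Esrra, 0.47 ± 0.76 for Esrrb, 0.74 ± 0.44 for Esrrg, 0.81 ± 0.71 for Ppara and 2.18 ± 0.87 for Ppargc1a. Glycolysis fell in 3 of 12 (10 adjusted over the list alone, median -0.94, camera adjusted p = 1.32e-16) and the hypoxia response in 2 of 19 (14 adjusted over the list alone, median -0.99, camera adjusted p = 3.32e-20), and both held with an adjusted p = 0.0165 with an estimated correlation. Resident macrophage markers had 2 up and 1 down of 10, with 5 and 1 adjusted over the list alone (median 0.61, camera adjusted p = 0.000907, and an adjusted p = 0.152 with an estimated correlation). Oxidative phosphorylation had 0 of 32 called and 0 adjusted over the list alone, with Atp5f1b at 0.24 ± 0.27 (median 0.33, camera adjusted p = 4.55e-05), and cardiomyocyte markers 0 of 14 called and 0 adjusted over the list alone, with Actc1 at 0.63 ± 0.41 (median 0.69, camera adjusted p = 0.00173), both with an adjusted p = 0.603 with an estimated correlation. In all 57 genes were called, 17 up and 40 down, 50 of them by at least 1 on the log2 scale. The count was 0 without MI24h_F replicate 2 or MI6h_F replicate 1, 2 without MI24h_F replicate 4 and 7 without MI6h_F replicate 4, so each of the 13 named calls was lost in at least 1 of these. MI24h_F replicate 1 and MI6h_F replicate 2 ended 2 calls each, among them that of Igf1, and Slc26a10 had 2.22 without MI6h_F replicate 1. A fit of only the groups compared lost 5 of the 13. Of the 59 genes called without F, 58 had the same sign with F, and 6 up and 19 down were called in both, against 0.0188 and 0.157 by chance.

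Early and late reperfusion were compared to ask what the longer ischemia, with its shorter reperfusion, adds. All tissue was collected at 24 h, so effects of ischemia time and of reperfusion time cannot be told apart. Some contractile, respiratory and mitosis genes were higher in MI1h_R than in MI6h_R. The ventricular myosin light chain Myl2 was higher by 4.78 ± 0.90 on the log2 scale and Actc1 by 1.79 ± 0.42. The respiratory genes Cox6c, Ndufs4, Cox8b and Ndufa4 were higher by 1.51 ± 0.30, 1.06 ± 0.22, 2.06 ± 0.47 and 1.17 ± 0.29, and Bub1, Nusap1 and Ube2c of mitosis by 1.18 ± 0.24, 2.09 ± 0.42 and 1.77 ± 0.43. Usp18 was higher by 3.40 ± 0.85. Cd163, the vessel peptide Apln, the scaffold protein gene Akap12 and the keratin Krt7 were lower, with -3.06 ± 0.58, -2.48 ± 0.39, -2.16 ± 0.27 and -2.35 ± 0.36. Short transcripts were higher as well, among them Rpl41, ATP8, Rps28 and Rps27 with 4.55 ± 0.64, 3.63 ± 0.67, 3.16 ± 0.62 and 2.20 ± 0.45. Without MI1h_R replicate 41 Rpl41 had 3.11, ATP8 2.10, Rps28 2.33 and Myl2 4.05, while Myl2 had 5.39 without MI6h_R replicate 11 and Cox8b 2.74 without MI6h_R replicate 31. The receptor genes were not called by edgeR, with -0.18 ± 0.16 for Esrra, -0.43 ± 0.67 for Esrrb, 0.64 ± 0.44 for Esrrg, -0.19 ± 0.69 for Ppara and 0.59 ± 0.82 for Ppargc1a. Oxidative phosphorylation rose in 4 of 32 (16 adjusted over the list alone, median 0.62, camera adjusted p = 4.35e-10), cell cycle genes in 3 of 19 (13 adjusted over the list alone, median 1.10, camera adjusted p = 1.67e-07) and the interferon response in 1 of 21 (20 adjusted over the list alone, median 2.36, camera adjusted p = 8.68e-08). Sarcomere genes rose in 2 of 16, with 6 up and 1 down adjusted over the list alone (median 0.67, camera adjusted p = 0.000251). These 4 lists had an adjusted p = 0.79 with an estimated correlation. In all 283 genes were called, 148 up and 135 down, 167 of them by at least 1 on the log2 scale. Directions rested on the scaling, with 74 up and 106 down by library size alone and 90 up and 876 down on TPM, where the median of all genes was -0.23. The count fell to 62 without MI1h_R replicate 11, 22 without MI1h_R replicate 31, 25, 24 and 112 without MI6h_R replicates 11, 21 and 31, 138 and 175 without MI1h_F replicates 4 and 5, 131 without MI24h_F replicate 2 and 164 without MI6h_F replicate 2. It rose to 1281 without MI1h_R replicate 41 and to 536 and 481 without Sham replicates 11 and 31. A fit of only the groups compared lost 7 of the 18 named calls, that of Rpl41 included, and removing the length trend, tried after the data were seen, those of Ndufs4, Cox8b, Ndufa4, Ube2c and Usp18. Rpl41, Apln, Akap12 and Krt7 kept their calls whichever library was left out, and the other 14 named calls were lost without MI6h_R replicate 21. MI24h replicate 21, MI1h_F replicate 1 and MI6h_F replicate 4 also ended the call of Ndufa4, and MI1h_F replicate 1 that of Usp18.

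With F, edgeR called 0 genes between early and late reperfusion, where 1597 genes had an unadjusted p under 0.05, DESeq2 called 83 and limma-voom with quality weights 1392. Leaving out MI6h_F replicate 1 gave 233 and leaving out MI24h_F replicate 1 gave 1. Actc1 and Mb had 1.48 ± 0.42 and 1.24 ± 0.42 on the log2 scale, the ATP synthase gene Atp5f1b 0.69 ± 0.27 and the neutrophil gene S100a9 -0.77 ± 0.51, and without MI6h_F replicate 1 Actc1 was called. Esrra had 0.32 ± 0.16, Esrrb 1.77 ± 0.69, Esrrg 0.50 ± 0.43, Ppara 0.42 ± 0.68 and Ppargc1a 0.80 ± 0.78. Limma-voom called Esrrb, Atp5f1b, Actc1 and Mb, and DESeq2 Actc1. With no member called by edgeR over all genes, oxidative phosphorylation had 16 of 32 up adjusted over the list alone (median 0.65, camera adjusted p = 6.51e-13), cardiomyocyte markers 12 of 14 up adjusted over the list alone (median 1.21, camera adjusted p = 1.39e-09) and neutrophil markers 4 of 14 down adjusted over the list alone (median -1.16, camera adjusted p = 3.99e-06). These 3 lists had an adjusted p = 0.438 with an estimated correlation.

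**Figure D4:**
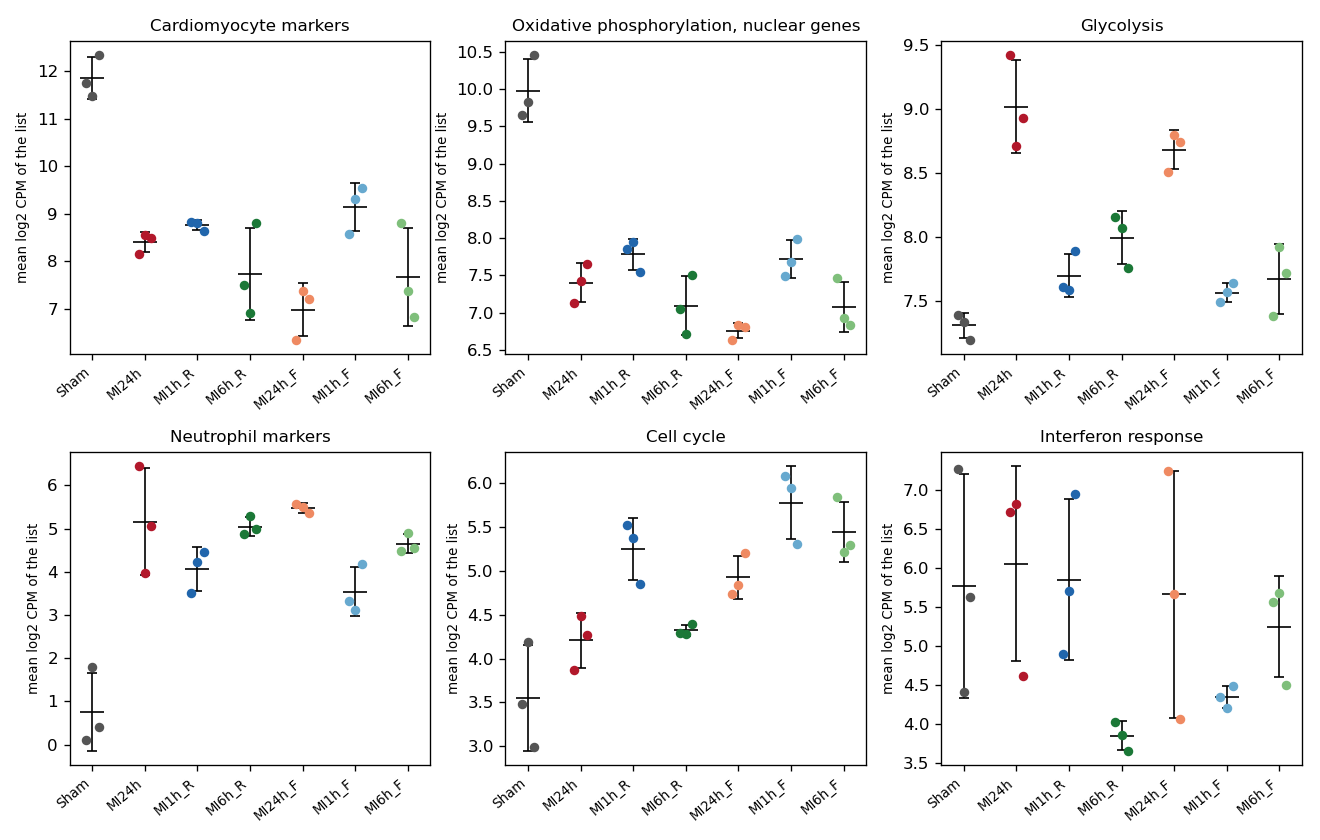
Mean log2 CPM of 6 gene lists; points are libraries, horizontal bars group means and error bars the SD over 3 libraries. Cardiomyocyte and oxidative scores are highest in Sham, and interferon scores spread from 4.61 to 6.82 within MI24h.

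The groups with F were compared with those without it, injury by injury, to ask what the addition changes. Under permanent ligation muscle and respiratory genes were lower with F, and genes of dividing cells were higher. The complex III gene Uqcr11 fell by 2.24 ± 0.32 on the log2 scale, Cox5b by 1.73 ± 0.27, Ndufa8 by 1.29 ± 0.23 and the mitochondrial Chchd10 by 2.20 ± 0.55. The heart transcription factor Nkx2-5 fell by 2.01 ± 0.38, the stretch sensor Csrp3 by 1.97 ± 0.44 and Smpx by 1.49 ± 0.36. Esrra fell by 0.99 ± 0.16 (edgeR adjusted p = 0.00276), the ERR target Slc25a4, an ADP carrier, by 1.53 ± 0.34 and the PPARα target Cpt1b by 1.76 ± 0.55. The other receptor genes were not called by edgeR, with -1.89 ± 0.72 for Esrrb (adjusted p = 0.0918), -0.40 ± 0.45 for Esrrg, -0.10 ± 0.72 for Ppara and -0.63 ± 0.90 for Ppargc1a. The mitosis genes Bub1, Cenpf and Ncapg rose by 1.14 ± 0.24, 1.78 ± 0.49 and 2.06 ± 0.34, the lipoxygenase Alox15 by 2.22 ± 0.66 and the red cell haem gene Alas2 by 2.08 ± 0.60. Oxidative phosphorylation fell in 12 of 32 (17 adjusted over the list alone, median -0.64, camera adjusted p = 9.3e-06), cardiomyocyte markers in 7 of 14 (12 adjusted over the list alone, median -1.43, camera adjusted p = 4.54e-05) and reported ERR targets in 3 of 22 (5 adjusted over the list alone, median -0.75, camera adjusted p = 0.00155). Sarcomere genes fell in 8 of 16, with 13 down and 1 up adjusted over the list alone (median -1.34, camera adjusted p = 0.000123), and cell cycle genes rose in 4 of 19 (6 adjusted over the list alone, median 0.67, camera adjusted p = 0.000123). These 5 lists had an adjusted p = 0.899 with an estimated correlation. PPARA targets fell in 1 of 28, 0 adjusted over the list alone (median -0.44, camera adjusted p = 0.107). In all 1523 genes were called, 609 up and 914 down, 498 of them by at least 1 on the log2 scale. Calls went with transcript length, with 25 up and 139 down among the 1175 shortest genes and 122 up and 29 down among the 1175 longest. With the length trend of each library removed, an alternative chosen after the data were seen, Uqcr11 had -2.00, Cox5b -1.51 and Ndufa8 -1.04, all still called. The count was 961, 876 and 854 without MI24h replicates 11, 21 and 41, and 316, 935 and 953 without MI24h_F replicates 1, 2 and 4. Esrra, Cox5b, Ndufa8, Uqcr11, Nkx2-5, Bub1 and Ncapg kept their calls whichever library was left out, and MI24h_F replicate 1 ended 7 of the 15 named calls, including Chchd10, Csrp3, Slc25a4 and Smpx. Each of the 6 libraries compared ended the call of Cpt1b when left out, as did MI1h_R replicate 11 and MI1h_F replicate 4. Those of Alox15 and Alas2 were lost without MI24h replicate 21 or 41 or MI24h_F replicate 1 or 4, and that of Cenpf without any 1 of the MI24h libraries or MI24h_F replicate 4. Alox15 had 3.02 without MI24h replicate 11 and Alas2 1.49 without MI24h_F replicate 4.

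After early reperfusion edgeR called 9 genes between the groups with and without F, 3 up and 6 down, 7 of them by at least 1 on the log2 scale. There 1917 genes had an unadjusted p under 0.05, DESeq2 called 314 and limma-voom with quality weights 2776. The clock repressor Nr1d1 rose by 1.81 ± 0.31 (edgeR adjusted p = 0.0297). The ribosomal transcript Rpl41 fell by 5.60 ± 0.69 (edgeR adjusted p = 0.000993), the folding factor Pfdn2 by 1.23 ± 0.21, and the RNA-binding Hnrnpdl and the anchoring protein gene Akap8 by 0.85 ± 0.15 and 0.78 ± 0.12. Esrra had -0.50 ± 0.16 (edgeR adjusted p = 0.169), Esrrb 1.14 ± 0.67, Esrrg 0.79 ± 0.44, Ppara 0.78 ± 0.69 and Ppargc1a 1.32 ± 0.80, none of them called by edgeR, while limma-voom called Esrra, Ppargc1a and Col3a1. Fibroblast markers had 0 of 16 called by edgeR and 8 up adjusted over the list alone, with Col3a1 at 1.10 ± 0.37 (median 0.73, camera adjusted p = 4.22e-06, and an adjusted p = 0.705 with an estimated correlation). The interferon response had 0 of 21 called and 8 down adjusted over the list alone, with Irf7 at -2.62 ± 0.98 (median -1.66, camera adjusted p = 7.8e-06, and an adjusted p = 0.729 with an estimated correlation). On TPM 8 genes were up and 5 down, where the median of all genes was 0.17. The count was 3, 2 and 2 without MI1h_F replicates 1, 4 and 5, 4 and 3 without MI1h_R replicates 31 and 41, 4 without MI24h_F replicate 2, 92 without Sham replicate 11 and 15 without Sham replicate 31. A fit of only the groups compared lost all 5 named calls. Rpl41 kept its call whichever library was left out, with -4.16 without MI1h_R replicate 41, and the other 4 named calls were lost without any 1 of the MI1h_F libraries. MI1h_R replicate 11 also ended the call of Nr1d1 and Sham replicate 41 that of Hnrnpdl.

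After late reperfusion F went with higher mitosis genes and lower Esrra. Bub1, Nusap1, Cenpf and the spindle motor Kif23 rose by 1.69 ± 0.24, 2.64 ± 0.43, 2.39 ± 0.49 and 2.23 ± 0.36 on the log2 scale, and the matrix genes Col1a1 and Lum by 2.00 ± 0.37 and 1.89 ± 0.40. Esrra fell by 1.00 ± 0.16 (edgeR adjusted p = 0.00363), Cd163 by 2.95 ± 0.58, the cytokine brake Socs3 by 2.14 ± 0.42, the muscle stress gene Xirp1 by 1.89 ± 0.38 and the short transcript Naa38 by 2.18 ± 0.41. Esrrb had -1.06 ± 0.69, Esrrg 0.93 ± 0.44, Ppara 0.17 ± 0.68 and Ppargc1a 1.12 ± 0.81, none called, but Ppargc1a was called at 3.23 without MI6h_R replicate 31. Cell cycle genes rose in 11 of 19 (12 adjusted over the list alone, median 1.25, camera adjusted p = 3.61e-08), fibroblast markers in 4 of 16 (5 adjusted over the list alone, median 0.26, camera adjusted p = 0.0379) and the interferon response in 1 of 21 (0 adjusted over the list alone, median 1.41, camera adjusted p = 0.00089). These 3 lists had an adjusted p = 0.99 with an estimated correlation. In all 1130 genes were called, 460 up and 670 down, 376 of them by at least 1 on the log2 scale, and on TPM 266 up and 979 down (median of all genes -0.11). The count was 540 and 258 without MI6h_F replicates 1 and 2 and 338, 461 and 649 without MI6h_R replicates 11, 21 and 31. The call of Lum was lost without MI6h_F replicate 1, where Cenpf had 1.80 and Col1a1 1.33, and the other 10 named calls were kept whichever library was left out. The F effects under permanent ligation and after late reperfusion share no library. In both, 271 genes were up and 386 down against 23.9 and 52.2 by chance, with 0 in opposite directions. A handling difference would also be shared, and chance values here and above assume independent genes.

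Averaged over the 3 injuries, Esrra, stress and short transcripts were lower with F. Mitosis, some matrix and red cell genes were higher, and no PPARα target was called. F and any difference in handling cannot be told apart, since F groups carry another range of replicate numbers. Calls went with length, with 240 down and 72 up among the 1175 shortest genes and 69 down and 242 up among the 1175 longest. Esrra fell by 0.83 ± 0.09 on the log2 scale (edgeR adjusted p = 4.14e-05). The means of the other receptor genes were not called by edgeR, with -0.60 ± 0.40 for Esrrb, 0.44 ± 0.25 for Esrrg, 0.28 ± 0.40 for Ppara and 0.60 ± 0.48 for Ppargc1a, which was called without MI6h_R replicate 31. Of 28 PPARA targets edgeR called 0, and 0 adjusted over the list alone (median -0.10, camera adjusted p = 0.919), with -0.24 ± 0.18 for the lipid droplet gene Plin2. Cenpf, Nusap1, Bub1 and Mki67 rose by 1.91 ± 0.28, 1.70 ± 0.24, 1.16 ± 0.14 and 1.24 ± 0.21, and the matrix genes Col1a1, Col1a2 and Lum by 1.44 ± 0.21, 0.90 ± 0.17 and 1.16 ± 0.23. Alox15 rose by 2.32 ± 0.39 and the red cell genes Slc4a1, Alas2 and Ahsp by 2.12 ± 0.44, 1.88 ± 0.35 and 2.32 ± 0.48. The receptor of the cytokine TWEAK, Tnfrsf12a, fell by 1.61 ± 0.21, the wall stress genes Xirp1 and Nppb by 1.35 ± 0.22 and 0.77 ± 0.19, and the AP-1 genes Jund, Junb and Fosl1 by 0.70 ± 0.14, 0.84 ± 0.17 and 0.85 ± 0.17. Cox5b and Ndufb8 of the respiratory chain fell by 1.20 ± 0.15 and 0.80 ± 0.13, and the short transcripts Naa38, Cops9, Tomm7 and Pfdn6 by 1.90 ± 0.23, 1.73 ± 0.19, 1.63 ± 0.28 and 1.59 ± 0.18. The clock gene Nr1d1 rose by 1.03 ± 0.18 and its counterpart Per1 fell by 0.82 ± 0.17.

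Cell cycle genes rose in 13 of 19 (14 adjusted over the list alone, median 0.92, camera adjusted p = 8.88e-07), fibroblast markers in 7 of 16 (8 adjusted over the list alone, median 0.33, camera adjusted p = 0.00181) and erythroid genes in 4 of 4 (4 adjusted over the list alone, median 2.00, camera adjusted p = 0.0044). Immediate early genes fell in 9 of 18 (12 adjusted over the list alone, median -0.49, camera adjusted p = 0.00138). These 4 lists had an adjusted p = 0.91 with an estimated correlation. The fetal gene programme fell in 6 of 12 (6 adjusted over the list alone, median -0.60, camera adjusted p = 0.0082, and an adjusted p = 0.919 with an estimated correlation) and oxidative phosphorylation in 9 of 32 (9 adjusted over the list alone, median -0.24, camera adjusted p = 0.0382, and an adjusted p = 0.988 with an estimated correlation). Clock genes had 4 up and 5 down of 15, as adjusted over the list alone (median -0.05, camera adjusted p = 0.919). In all 3178 genes were called, 1331 up and 1847 down, 318 of them by at least 1 on the log2 scale. All 26 named calls, Esrra included, were kept whichever library was left out.

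Whether the F effect differed between injuries was tested as a difference of differences. Between early reperfusion and permanent ligation edgeR called 0 genes, with 1990 at an unadjusted p under 0.05, 224 by DESeq2 and 2003 by limma-voom with quality weights. The count was 29 without MI1h_F replicate 1 and 1 without MI1h_R replicate 11 or MI6h_F replicate 2. Muscle and oxidative genes lay on the positive side, with 1.52 ± 0.58 for Actc1, 0.76 ± 0.39 for Atp5f1b and 1.33 ± 0.47 for Slc25a4 on the log2 scale. Esrra had 0.50 ± 0.23, Esrrb 3.02 ± 0.98 (edgeR adjusted p = 0.195), Esrrg 1.19 ± 0.62, Ppara 0.88 ± 1.00 and Ppargc1a 1.95 ± 1.20. Limma-voom called Esrra, Esrrb, Actc1 and Slc25a4. No member of 3 lists was called by edgeR, with 10 of 14 cardiomyocyte markers up adjusted over the list alone (median 1.73, camera adjusted p = 3.88e-06), 0 of 22 reported ERR targets adjusted over the list alone (median 1.05, camera adjusted p = 0.000117) and 1 of 32 oxidative phosphorylation genes up adjusted over the list alone (median 0.57, camera adjusted p = 0.000117), each with an adjusted p = 0.686 with an estimated correlation. Between late reperfusion and permanent ligation edgeR called 0 genes, with 425 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom with quality weights. Actc1 and Atp5f1b had 1.83 ± 0.58 and 0.56 ± 0.39 there, and Esrra 0.00 ± 0.23, Esrrb 0.82 ± 1.00, Esrrg 1.33 ± 0.63, Ppara 0.27 ± 0.99 and Ppargc1a 1.75 ± 1.21. Cardiomyocyte markers had 0 of 14 adjusted over the list alone (median 1.36, camera adjusted p = 5.97e-09) and oxidative phosphorylation 0 of 32 adjusted over the list alone (median 0.56, camera adjusted p = 1.44e-12), both with an adjusted p = 0.705 with an estimated correlation. Between early and late reperfusion edgeR called 1 gene, Rpl41, at -6.13 ± 0.89 (adjusted p = 0.022), or -4.69 without MI1h_R replicate 41. The count was 2 without MI1h_F replicate 1, 3 without MI1h_R replicate 11, and 0 without MI1h_F replicate 4 or 5, MI6h_F replicate 1 or 2, or any 1 of the MI6h_R libraries. Esrra had 0.50 ± 0.23 there, Esrrb 2.20 ± 0.96, Esrrg -0.14 ± 0.62, Ppara 0.61 ± 0.97 and Ppargc1a 0.20 ± 1.13. The interferon response had 18 of 21 down adjusted over the list alone and 0 called, with Ifi27 at -1.69 ± 0.81 (median -3.31, camera adjusted p = 3.3e-12, and an adjusted p = 0.978 with an estimated correlation).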

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

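The removal of the length trend was chosen only after the result was seen, as were the checks of the Rpl41 fold with it. Rpl41, a very short ribosomal transcript, differed in its F effect between early and late reperfusion by -6.13 ± 0.89 on the log2 scale (edgeR adjusted p = 0.022), which a test of the difference itself picked out. It stood at 12.9, 23.2 and 110 CPM in the MI1h_R libraries. With a smooth length trend of each library removed the difference was -5.65 ± 0.88 (edgeR adjusted p = 0.0537), so the fold moved by less than its error and the call ended because that small move crossed the threshold. Without MI1h_R replicate 41, the library at 110 CPM, it was -4.69 ± 0.62 (edgeR adjusted p = 0.00709), a smaller difference that was still called. Over all alternatives run for it the adjusted p ranged from 4.62e-09 to 0.136 and the fold kept its sign.

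The wider pattern is that short transcripts were higher in MI1h_R than in MI6h_R. Among the 1175 genes with the shortest transcripts 68 were called up and 6 down. Removing the trend left 29 called up, so length-dependent recovery of transcripts is a candidate explanation for a part. Whether it is the whole cause stays open, since no chance count was made for the 29. MI1h_R replicate 41 alone is argued against, since the shortest genes had a median of 0.38 with it and 0.43 without it. Removing the trend also removes biology that follows length, because ribosomal and respiratory genes are short. The difference in ischemia time, and with it in reperfusion time, stays open as an untested explanation.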

How the results depend on the processing

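The removal of the length trend and the use of identical genes only once were chosen after the data were seen. The 16 counts of called genes stayed within 1.5-fold of their value with median-of-ratios factors, without a filter, without mitochondrial genes and with identical genes used once. Where a count or sign changed, the cause was not tested, except that fits of fewer libraries have fewer degrees of freedom. With limma-voom and quality weights the counts were 1509 for MI1h_R against MI24h, 3020 for MI1h_R against MI6h_R, 2916 for MI24h_F against MI24h, 2776 for MI1h_F against MI1h_R, 2007 for MI6h_F against MI6h_R, 4815 for MI1h_F against MI24h_F, 344 for MI6h_F against MI24h_F and 1392 for MI1h_F against MI6h_F, and the F effect differed between MI1h and MI24h in 2003 genes and between MI1h and MI6h in 1271. DESeq2 gave, for MI1h_R against MI24h, 1047, MI6h_R against MI24h 186, MI1h_R against MI6h_R 916, MI1h_F against MI1h_R 314, MI6h_F against MI24h_F 195 and MI1h_F against MI6h_F 83, and for the F differences 224 (MI1h and MI24h), 1 (MI6h and MI24h) and 60 (MI1h and MI6h). Fits of only the groups compared gave 3807 for MI1h_R against Sham, 0 for MI1h_R against MI24h, 5 for MI6h_R against MI24h, 86 for MI1h_R against MI6h_R, 3458 for MI1h_F against MI24h_F, 1 for MI1h_F against MI6h_F and 2 for the F difference of MI1h and MI6h. For MI1h_R against MI6h_R library size alone gave 180 and TPM 966. The F difference of MI1h and MI6h lost its gene on TPM (0) and without the length trend (0), and without it MI1h_F against MI1h_R had 15. A replicate block over the 12 libraries without F gave 4033 and 4292 for MI24h and MI6h_R against Sham, 2 for MI1h_R against MI24h, 2 for MI6h_R against MI24h and 4 for MI1h_R against MI6h_R, where no replicate block on these 12 gave 73, 13 and 13 for the last 3. Over the 9 libraries with F the replicate block gave 236 for MI1h_F against MI24h_F, and no replicate block gave 2980 for it and 139 for MI6h_F against MI24h_F. With each library left out, counts ran from 68 to 943 for MI1h_R against MI24h, 14 to 110 for MI6h_R against MI24h, 22 to 1281 for MI1h_R against MI6h_R, 316 to 1800 for MI24h_F against MI24h, 2 to 92 for MI1h_F against MI1h_R, 258 to 1461 for MI6h_F against MI6h_R, 644 to 2131 for MI1h_F against MI24h_F, 0 to 73 for MI6h_F against MI24h_F, 0 to 233 for MI1h_F against MI6h_F, 0 to 29 for the F difference of MI1h and MI24h and 0 to 3 for that of MI1h and MI6h. The other 5 counts stayed within 1.5-fold. The share of injury genes that moved towards Sham was 86.1% for MI1h_F against MI24h_F among genes changed by at least 1 on the log2 scale, and with a library left out it ran from 78.8% to 81.6%, and for MI6h_F against MI24h_F from 63.0% to 78.0%. Of 323 named folds, DESeq2 kept the call and sign of 317 of 321, median-of-ratios factors 323, library size alone 306, TPM 290, limma-voom 297, length trend removed 312 and only the groups compared 261 of 322, and over all libraries left out 6463 of 6783. Of 104 list medians library size alone moved 36, all upwards and against Sham. Library size alone reversed the endothelial median of MI24h against Sham (0.39) and, for MI6h_R against MI24h, Esrra (0.01). TPM reversed Esrra for MI24h and MI6h_R against Sham (0.26 and 0.33) and MI6h_R against MI24h (0.07), Ppargc1a there (-0.30), Esrrg for MI1h_R against MI24h (-0.04) and in the F difference of MI1h and MI6h (0.22). limma-voom reversed Ppara for MI1h_R and MI6h_R against MI24h (-0.11 and -0.06), Ppargc1a for the latter (-0.88), Esrrb for MI6h_F against MI24h_F (-0.07) and Esrrg in the F difference of MI1h and MI6h (0.15), and removing the length trend reversed Esrra in that of MI6h and MI24h (0.01). With a library left out, uncalled folds changed sign for Esrrg (-0.15 to 0.34) and Ppara (-0.08 to 0.65) in MI1h_R against MI24h, Esrrb (-0.91 to 0.02), Ppara (-0.46 to 0.93) and Ppargc1a (-1.68 to 0.90) in MI6h_R against MI24h, Esrrb (-1.11 to 0.12) and Ppara (-0.62 to 0.81) in MI1h_R against MI6h_R, Esrrb (-0.17 to 1.11), Ppara (-0.20 to 1.22) and Atp5f1b (-0.05 to 0.41) in MI6h_F against MI24h_F, and Ppara in MI24h_F against MI24h (-0.42 to 0.20), in MI6h_F against MI6h_R (-0.84 to 1.16) and in the averaged F effect (-0.05 to 0.61). In the F differences this held for Esrra (-0.07 to 0.04) and Ppara (-0.73 to 1.27) between MI6h and MI24h, and for Esrrg (-0.45 to 0.47), Ppara (-0.38 to 1.62) and Ppargc1a (-1.91 to 1.31) between MI1h and MI6h. With 3 libraries per group the simulated test mostly missed changes near 1.5-fold. Symbols with too few counts were not assessed.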

Other observations

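The tests of a swap and of surviving muscle in MI6h_F replicate 1, and both tests of the muscle genes in MI24h, were chosen only after the result was seen. Interferon genes varied between libraries of the same group. Their mean log2 CPM ran from 4.41 to 7.26 in Sham and from 4.61 to 6.82 in MI24h, and was low in all 3 libraries of MI6h_R, between 3.66 and 4.03. The F groups differed in short transcripts too, as given above.

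MI6h_F replicate 1 resembled the MI1h_F libraries, with a mean correlation of 0.977 to them against 0.961 to its own group. A swap between both groups is argued against, since 0 of the MI1h_F libraries correlated better with MI6h_F than with their own group. On the 249 genes called between MI1h_R and MI6h_R with the length trend removed the library lay 0.744 of the way from the others of its group to MI1h_F, with an SD of 0.491, so a single wrong label cannot be told apart from ordinary spread with so few libraries. More surviving muscle stays open. It would dilute neutrophil and fibroblast markers alike, and their difference lay -1.05 from the rest of MI6h_F, within 2 pooled SD of 0.82. Yet the fibroblast score was higher, 8.36 against 7.52 and 7.62.

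Cardiomyocyte and oxidative genes were lower in MI24h than in Sham. A lower share of cardiomyocytes alone would raise the markers of all other cells alike, but the medians of neutrophil and fibroblast markers lay 6.22 apart on the log2 scale (pooled SD 1.47). Dilution by incoming leukocytes alone would lower all resident cells alike, but the cardiomyocyte median lay 2.86 below the endothelial one (-2.86, pooled SD 1.17). Cell loss together with infiltration stays open, and so does lower transcription per cell, which bulk tissue did not test.

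Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 6371 genes for MI24h against Sham (highest other 910), 5809 for MI1h_R against Sham (218) and 6721 for MI6h_R against Sham (0). It called 59 for MI6h_R against MI24h (0), 283 for MI1h_R against MI6h_R (1), 1523 for MI24h_F against MI24h (1), 9 for MI1h_F against MI1h_R (0) and 1130 for MI6h_F against MI6h_R (122). With F it called 1832 for MI1h_F against MI24h_F (0), 57 for MI6h_F against MI24h_F (0) and 0 for MI1h_F against MI6h_F, where all 10 splits gave 0. For MI1h_R against MI24h the real 507 was exceeded by 1 other split with 1095 genes, so 2 of the 10 were as large. That split sets MI24h replicates 11 and 21 with MI1h_R replicate 41 against the rest, the libraries with higher interferon scores, and points to a structure of the samples. For the averaged F effect 1 of 100 splits, the real one, gave as many as 3178 (highest other 874), so chance is unlikely there. For the difference of F effects between MI1h and MI6h 5 of 100 splits gave at least the real 1 (highest other 122), so chance is not excluded. For MI1h against MI24h (highest other 319) and MI6h against MI24h (highest other 3018) the real count was 0, which 100 of 100 splits reach by construction, so the splits say nothing about it. The split with 3018 genes exchanges F and no F in all MI6h libraries and in none of MI24h, which turns the difference into a sum of F effects.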
